A study of Homo sapiens with 6 samples.

How the data were processed

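RNA-seq and Ribo-seq (sequencing of the mRNA fragments that ribosomes protect from nuclease) were performed on 786-O cells labelled EV, WT and MT, with 1 library per label and assay. Per the labels' protocols, RNA was extracted with TRIzol, elongation was blocked with cycloheximide before lysis, footprints were made with RNase I, ribosomal RNA was removed with antisense DNA probes, and libraries were made with NEBNext kits, one for small RNA for Ribo-seq. Cycloheximide added to living cells can shift footprints along mRNAs. The labels name total RNA as the molecule of the RNA-seq samples and polyadenylated RNA for Ribo-seq; which RNA selection RNA-seq used is not given in the sources used here, and replication-dependent histone mRNAs, which lack a poly(A) tail, had medians of 0.072 to 0.145 FPKM there and 889.7 to 973 TPM in Ribo-seq. The design text names 3 dishes per condition; whether they were pooled into each library is not given. The aligner, the counting of footprints, the annotation and any trimming are not given in the sources used here. The build named in the submitters' processing notes is human genome build 18, although the gene symbols in the table are recent ones, so no coordinates are given.

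One deposited table held 20307 rows with 1 column per library. The RNA-seq columns carry no unit in the file headers. They were read as FPKM, fragments scaled to transcript length and library size, because the deposited columns sum to between 459938 and 469859; TPM over a larger set of genes is not excluded. The deposited Ribo-seq columns are TPM, in which every library is scaled to one total, as each sums to 1000000. The design had allowed for raw counts, and since the values were normalized, the rule it gave for other units was used. No count-based test or interval was possible. Read totals are unknown. Spacing of low values gave a relative RNA-seq depth of 1.06 in WT and 1.05 in MT against EV. For Ribo-seq the smallest steps were 1.28 times (WT) and 0.943 times (MT) those of EV, so the WT library has the coarsest values. Genes above 0 in a single library had a median of 0.038 to 0.046 FPKM and 0.118 to 0.148 TPM, which is about the worth of 1 or a few reads, so that values near 1 TPM rest on few reads. A listed 0 does not always mean that a gene lacks mRNA, as ASNS was at 0 in all 3 Ribo-seq libraries with an mRNA value of 43.3 FPKM or more. Why it was listed at 0 was not examined.

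Columns were matched to samples by name, with labels kept as deposited. Rows without a gene name (605, 0.15% to 0.16% of the RNA-seq sums and 0.51% to 0.56% of Ribo-seq) and 7 symbols on several rows with different values were left out, which left 19669 genes, all found in the reference symbol table. Values were compared as deposited, on log2(value + 1), a scale that understates changes of low genes. A gene entered a comparison at 1 unit or more in at least 1 library compared, and counted as higher or lower at an absolute log2 difference of 1 or more. Translational efficiency was the difference of the 2 log2 ratios, with no model or test. Differences of genes at 100 units or more had a robust SD across genes of 0.11 to 0.13 (log2) in RNA-seq and 0.15 to 0.22 in Ribo-seq, which mixes real differences with error.

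Named genes followed a rule set before the data were examined. In each comparison they are the 8 highest and 8 lowest past the rule among genes with 10 units in 1 library (5 and 5 for translational efficiency), PHYHD1, the references ACTB, GAPDH, VHL, EPAS1, VEGFA and CCND1, and up to 4 members past the rule of each list described or, with none, its most abundant members. Genes chosen after their values were seen are marked as such; for lists with many medians given together, members are left out. Some genes that the rule selects are not reported here. The 42 gene lists were fixed at the same time. For each with 5 or more measured members, the median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean level, and a list stood apart below percentile 2.5 or above 97.5. These percentiles describe the libraries and are not p-values. Over the 9 comparisons 326 medians were placed, of which 122 stood apart, with 16.3 expected by chance. Members of a list vary together, so random lists understate the spread. Readthrough names, and some genes that share reads with near-identical copies, are reported as uncertain. Sequence similarity between genes was not examined, so other named genes may share reads too. In all, 73 readthrough names reached 1 unit.

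The procedure was tested on simulated libraries of WT over EV. For each fold change 50 genes were simulated, drawn only from genes at 10 units or more in EV. Of those changed 4-fold 100% passed the rule in both assays. Of those changed 2-fold upward 34% passed in RNA-seq (11004 genes in the step) and 42% in Ribo-seq (10658 genes). Recovery of genes under 10 units was not simulated. Simulated counting error alone took 0% of unchanged RNA-seq genes past the rule, and in Ribo-seq 0.642% of those at 1 to 10 units. In each assay a read was given the same value for all genes and both libraries. The alternatives tried were median-ratio scaling, minimum levels of 0.1 and 10 units and a pseudocount of 0.1, and, chosen after the data were seen, a minimum of 1 unit in every library compared and an exchange of the WT and MT labels in Ribo-seq. Intervals of correlations came from 1000 bootstrap draws of genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.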

Results

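Messenger RNA and ribosome-protected fragments were measured in 786-O cells, a clear cell renal carcinoma line that lacks functional VHL, the ubiquitin ligase subunit that marks hypoxia-inducible factors for degradation. There were 3 labels, EV (empty vector), WT and MT, each with 1 RNA-seq and 1 Ribo-seq library, so 6 libraries in all. The labels disagree about what WT and MT stand for. The series title gives PHYHD1-WT and, for MT, a PHYHD1 lacking the segment 107 to 130. The design text instead describes MT as overexpressing PHYHD1 and WT as untreated. The deposited column names, PHYHD1-WT and PHYHD1-MT, go with the title, though they do not name the deletion. PHYHD1 belongs to the family of iron- and 2-oxoglutarate-dependent dioxygenases. With 1 library per label and assay no difference has a replicate check, no p-value can be given, and each comparison is between libraries rather than conditions. A gene is called higher or lower below when its value, after adding 1, differed at least 2-fold, which is a rule of size and not a test. Genes at 1 unit or more numbered 10897, 10848 and 10854 in the EV, WT and MT RNA-seq libraries and 10413, 10400 and 10489 in the Ribo-seq libraries. The deposited values hold no read totals.

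PHYHD1 (ENSG00000175287.19) was close to absent in the EV libraries and abundant in the libraries labelled WT and MT. Its mRNA stood at 0.092 FPKM in EV, 118 FPKM in WT and 109.5 FPKM in MT, where the EV value is worth about 1 or a few reads, so no exact fold over it is given. In Ribo-seq it was listed at 0 in EV, at 222 TPM in WT and at 905 TPM in MT. MT therefore held 4.08 times the Ribo-seq value of WT with 0.931 times the mRNA value. The ratio of Ribo-seq to RNA-seq value was 1.88 in WT and 8.26 in MT. These ratios rest on the labels pairing the same cells in both assays. The high value in the library labelled WT, like its column name, goes against the description of that group as untreated cells with only endogenous PHYHD1. Libraries are referred to by label throughout. The deletion itself cannot be seen in values per gene.

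**Figure D1:**
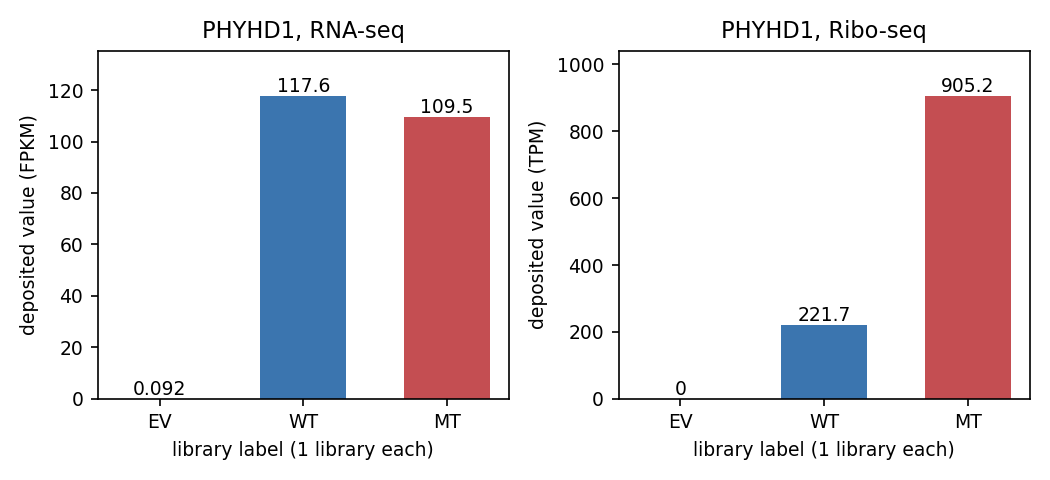
Deposited PHYHD1 values in the 6 libraries, as bars from 0, with RNA-seq in FPKM on the left and Ribo-seq in TPM on the right; each bar is 1 library, so there are no error bars. The RNA-seq values of WT and MT (118 and 109.5) are close to each other, while the Ribo-seq values are 222 and 905.

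Comparing the library labelled WT with EV asks what differed in mRNA level with PHYHD1 at the level of the WT label. PHYHD1 led the genes higher in WT, followed by EXOG, a mitochondrial nuclease (5.48 to 37.4 FPKM), and PTCD3, a protein of the small mitochondrial ribosomal subunit (31.9 to 113 FPKM). R3HDM2, the methionyl-tRNA synthetase gene MARS1 (73.4 to 215 FPKM), the Golgi tethering subunit COG6, the cap-binding protein gene NCBP3 and C15orf40 were the other named genes that were higher. Lower in WT were ASL, the argininosuccinate lyase of the urea cycle (40.9 to 13.2 FPKM), the spliceosomal core protein gene SNRPD3 (50.1 to 21.6 FPKM), DPM3, the sodium pump regulator FXYD2, the RNA polymerase I factor gene TAF1B and SMPDL3A. In all, 26 genes were higher and 29 lower of 11032 measured (9 and 6 at a minimum of 10 units). Of the 19 higher genes that were measured in both assays, 14 had a Ribo-seq difference of the same sign and 3 passed the rule there, and of the 19 lower ones 10 and 1 did. PTCD3 stood at 27.0 TPM in EV and 29.9 TPM in WT, and SNRPD3 at 200.4 and 204.6 TPM.

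The gene lists moved by small amounts in the same comparison. Heat shock genes had a median log2 ratio of 0.28, with 17 of 19 members above 0, and HSP90AB1 and HSPA8, the most abundant, stood at 843 and 676 FPKM in EV and 959 and 893 FPKM in WT. Ribosome biogenesis genes had a median of 0.26, with 36 of 40 above 0, and nucleolin (NCL) went from 489.8 to 594 FPKM. Both medians were above all 10000 random lists matched on level, as were those of tRNA modification enzymes (0.13) and translation initiation factors (0.12). S-phase genes (0.11), proteasome subunits (0.10), mitochondrial ribosomal proteins (0.06), selenoproteins (0.15), extracellular matrix genes (0.08) and NF-kappaB and inflammatory genes (0.13) also stood high. COL6A3, TNC and TAGLN, matrix and contractile genes at 2.95, 8.29 and 1.31 FPKM in WT, passed the 2-fold rule. Mitochondrially encoded mRNAs were low (median -0.24, 12 of 13 members below 0), and their share of the library was 16.8% in EV and 15.1% in WT. Low too were interferon-stimulated genes (-0.15), p53 targets (-0.13), peroxisome and fatty acid oxidation genes (-0.10), nuclear-encoded oxidative phosphorylation (-0.09), cholesterol and fatty acid synthesis (-0.09), hypoxia-inducible factor targets (-0.07) and cytosolic ribosomal proteins (-0.05). Of 36 lists 18 stood apart, with 1.8 expected by chance. With a minimum of 10 units the NF-kappaB median became -0.01 and the matrix and selenoprotein lists no longer stood apart, and the other settings gave between 15 and 177 genes past the rule.

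In the library labelled MT the mRNA differences from EV were fewer. PHYHD1, EXOG (31.8 FPKM in MT), PTCD3 (90.0 FPKM), C15orf40 and the exosome nuclease gene DIS3L (11.6 to 24.4 FPKM) were the named genes higher than in EV. ASL (13.7 FPKM), SNRPD3 (20.3 FPKM), TAF1B (9.92 FPKM) and NUDCD2 (15.3 to 6.66 FPKM) were lower. The rule was passed by 13 genes upward and 19 downward of 11016 (5 and 4 at a minimum of 10 units). Since both comparisons use the same EV library, part of what they share may stem from that library.

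Interferon-stimulated genes were the list farthest below 0 in MT over EV, with a median of -0.37 and 37 of 39 members below 0. RSAD2 (4.72 to 1.62 FPKM) and EPSTI1 (1.99 to 0.125 FPKM) passed the rule. Targets of ATF4, the transcription factor of the integrated stress response, had a median of -0.30 with 28 of 31 members below 0; SLC7A5 went from 341 to 285 FPKM and PSAT1 from 209 to 127 FPKM. Cytosolic aminoacyl-tRNA synthetases (-0.21, TARS1 from 246 to 210.0 FPKM), hypoxia-inducible factor targets (-0.17, 28 of 35 below 0) and mitochondrially encoded mRNAs (-0.23) were likewise below all 10000 random lists. Antigen presentation genes (-0.13), p53 targets (-0.10), S-phase genes (-0.09) and cytosolic ribosomal proteins (-0.03) were low by less. Higher in MT were proteasome subunits (0.12, 29 of 36 above 0), genes of the G2 and M phases (0.12, 37 of 40 above 0) and heat shock genes (0.10). The median of 5 renal tubule markers was high too (0.17), with 3 of them above 0 and 2 below. No member of the proteasome, G2 and M or ATF4 lists passed the 2-fold rule. In total 13 of 36 lists stood apart, with 1.8 expected by chance, and other settings gave 9 to 145 genes.

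Set against each other, the RNA-seq libraries labelled WT and MT differed in 56 of 11013 genes, with 32 higher and 24 lower in WT (12 and 3 at a minimum of 10 units). The named genes higher in WT were GRAMD4, COG6, NT5E (CD73, which makes extracellular adenosine; 25.5 FPKM in WT and 8.49 in MT), R3HDM2, NCBP3, transglutaminase 2 (TGM2; 19.9 and 7.09 FPKM), MARS1 and the complex I subunit gene NDUFA7 (29.8 and 11.9 FPKM). FXYD2 (9.55 and 23.2 FPKM), FILIP1L and the peroxisomal racemase gene AMACR (29.2 and 60.2 FPKM) were lower. NF-kappaB and inflammatory genes (median 0.28), interferon-stimulated genes (0.27, 30 of 38 above 0), ATF4 targets (0.26, 27 of 31), aminoacyl-tRNA synthetases (0.23, 19 of 20), S-phase genes (0.21, 39 of 40) and ribosome biogenesis genes (0.21, 35 of 40) all lay above all 10000 random lists. RSAD2 and TNC (8.29 FPKM in WT and 3.46 in MT) were among the members of the interferon and matrix lists past the rule. Extracellular matrix genes (0.13), heat shock genes (0.13), tRNA modification enzymes (0.14), genes of VHL-null renal carcinoma lines (0.13), initiation factors (0.09) and other mRNAs with a 5' terminal oligopyrimidine tract (0.07) were also high. Low in WT were cholesterol synthesis (-0.10), peroxisome and fatty acid oxidation (-0.08), G2 and M phase (-0.06), oxidative phosphorylation (-0.06) and the renal tubule marker list (-0.38). Of its 5 markers 3 were below 0 and 2 above, and only FXYD2 passed the rule. At a minimum of 10 units the matrix median was -0.01 and the NF-kappaB list fell just inside the random range (percentile 97.46), and other settings gave 15 to 198 genes.

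Ribosome-protected fragments differed more between libraries than mRNA did. In WT over EV 186 genes were higher and 173 lower of 10700 (59 and 31 at a minimum of 10 units). Besides PHYHD1, the named genes higher in WT were the sodium channel gene SCN8A (0.841 to 12.5 TPM), TVP23C (10.7 to 77.4 TPM), the MAP kinase phosphatase gene DUSP16 (3.98 to 30.3 TPM), CABLES1 (0.844 to 10.4 TPM), the zinc finger genes ZNF525 and ZNF417, and COMMD3-BMI1. RREB1, a zinc finger transcription factor of Ras signalling, was lower (18.7 to 1.72 TPM), as were DENND2B, NEMP2, the autophagy regulator AMBRA1 (14.3 to 3.91 TPM), the amino acid transporter gene SLC38A7, NOTCH2NLC, ARL2-SNX15 and the histone gene H3C3. The mRNA of DUSP16 was 6.06 FPKM in EV and 5.05 in WT, and that of RREB1 7.22 and 8.17. COMMD3-BMI1 and ARL2-SNX15 are readthrough names, TVP23C shares reads with one, and NOTCH2NLC and H3C3 have near-identical copies, so their values are uncertain. Genes under 10 units made up 74.9% of the calls.

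Genes of the G2 and M phases had the highest list median in this comparison (0.27, 34 of 40 above 0, above all 10000 random lists). The most abundant 2 members did not share that direction, with UBE2C at 724 and 684 TPM and BIRC5 at 441 and 387 TPM in EV and WT, whereas TOP2A, chosen after its values were seen, stood at 137 and 213 TPM. Proteasome subunits were high as well (0.12). Antigen presentation genes (-0.36, 14 of 16 below 0; CD74 from 4.19 to 1.49 TPM) and interferon-stimulated genes (-0.29, 34 of 42 below 0) were below all 10000 random lists, and RSAD2 (14.9 to 5.14 TPM), XAF1 (6.22 to 2.48 TPM), OAS1 (2.61 to 0.575 TPM) and OAS2 (2.38 to 0.210 TPM) passed the rule. NF-kappaB and inflammatory genes were low (-0.26), with CXCL8 at 27.8 TPM in EV and 12.8 in WT but REL at 3.2 and 8.41. Further low lists were genes of VHL-null renal carcinoma lines (-0.24), hypoxia-inducible factor targets (-0.21), immediate early genes (-0.15; FOS 3.11 to 0.405 TPM), extracellular matrix genes (-0.13) and cytosolic ribosomal proteins (-0.13). VEGFA, a hypoxia-inducible factor target, stood at 36.3 TPM in EV and 21.9 TPM in WT. Of 36 lists 10 stood apart, and other settings gave between 90 and 694 genes past the rule (90 at a minimum of 10 units).

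Ribo-seq values in MT over EV were higher for 182 genes and lower for 122 of 10737 (63 and 22 at a minimum of 10 units). After PHYHD1 the named genes that were higher were ST20-MTHFS, FAM72D, SCHIP1 (0.570 to 12.8 TPM), NOTCH2NLB, ARPIN-AP3S2, the actin acetyltransferase gene NAA80 (2.71 to 15.1 TPM) and the transcription factor gene ZBTB20 (2.76 to 13.8 TPM). RREB1 (1.54 TPM in MT), FAM72A, TMCC1 (16.7 to 4.49 TPM), NOTCH2NLC, the kinase gene STK17B (33.8 to 10.9 TPM), EIF2AK3, which encodes the endoplasmic reticulum stress kinase PERK (24.4 to 7.83 TPM) and RAMACL were lower. FAM72A and FAM72D, like the NOTCH2NL genes, are copies of one another, and ST20-MTHFS and ARPIN-AP3S2 are readthrough names. SCHIP1 mRNA was 0.144 FPKM in EV and 0 in MT, and RAMACL mRNA was listed at 0 in both. Few lists stood apart, 6 of 36 with 1.8 expected by chance. Extracellular matrix genes were high (0.15; COL6A3 0.109 to 1.25 TPM), though not at a minimum of 10 units (percentile 95.5). Mitochondrially encoded mRNAs were high too (0.14, 9 of 13 above 0), and MT-ATP8 stood at 11621 TPM in EV, 11487 in WT and 21537 in MT. The mitochondrially encoded share of Ribo-seq values was 1.38% in EV, 1.33% in WT and 2.39% in MT, and without MT-ATP8 it was 0.219%, 0.186% and 0.237%. Replication-dependent histones (-0.14, 36 of 44 below 0), cholesterol synthesis (-0.11), cytosolic ribosomal proteins (-0.09) and other terminal oligopyrimidine mRNAs (-0.09, percentile 2.81 at a minimum of 10 units) were low. The histone genes past the rule went the other way, H3C3 (46.5 to 97.7 TPM) and H2BC3 (4.59 to 12.1 TPM). Other settings gave 85 to 660 genes.

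Between the Ribo-seq libraries labelled WT and MT, 156 genes were higher and 187 lower in WT of 10752 (52 and 49 at a minimum of 10 units). TVP23C (77.4 TPM in WT and 6.30 in MT), its readthrough partner TVP23C-CDRT4, FAM72A, ARPIN, DUSP16 (30.3 and 3.64 TPM), CABLES1, SCN8A and the checkpoint clamp gene RAD9A (11.5 and 1.52 TPM) were higher. ST20-MTHFS, ARPIN-AP3S2, the histone genes H4C13, H3C3 and H2BC3, plakoglobin (JUP; 0.712 and 10.9 TPM), the interferon-induced IFITM2 (9.47 and 44.1 TPM) and PHYHD1 were lower. Genes that share reads with a readthrough name (ARPIN, TVP23C) and near-identical copies (FAM72A, the histone genes) are uncertain here and below; ARPIN and ARPIN-AP3S2 went opposite ways. Antigen presentation genes (-0.34, 16 of 17 below 0), interferon-stimulated genes (-0.27, 28 of 41 below 0) and extracellular matrix genes (-0.23, 30 of 35 below 0) were below all 10000 random lists. Immediate early genes (-0.31), mitochondrially encoded mRNAs (-0.30), NF-kappaB and inflammatory genes (-0.29, with TNFAIP3 at 0.901 and 3.80 TPM), hypoxia-inducible factor targets (-0.14) and cytosolic ribosomal proteins (-0.05) were low. The median of 7 renal tubule markers was low too (-0.39), with 5 of them below 0 and 2 above. G2 and M phase genes (0.23, 33 of 40 above 0) and proteasome subunits (0.11) were high. In all 11 of 37 lists stood apart, against 1.85 expected by chance, and other settings gave 101 to 727 genes past the rule.

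**Figure D2:**
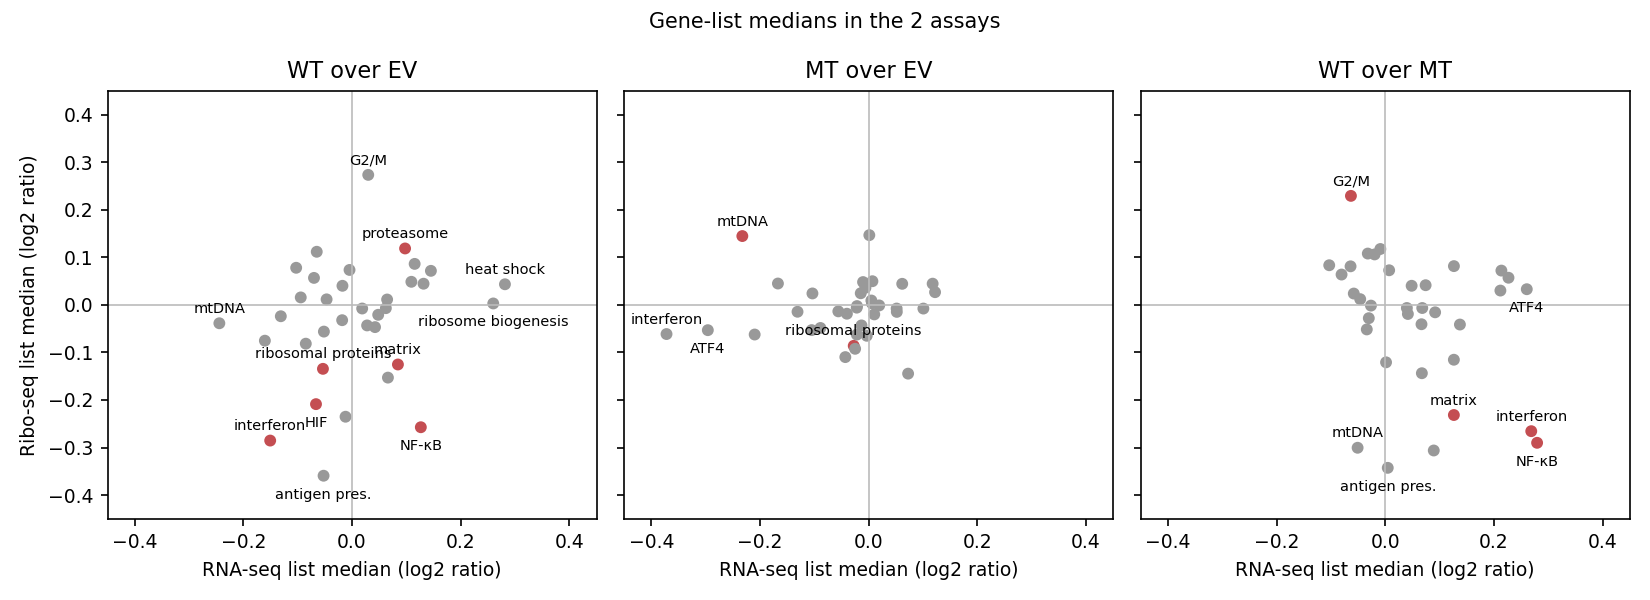
Each point is 1 gene list, placed by the median log2 ratio of its members in RNA-seq (horizontal axis) and Ribo-seq (vertical axis), with 1 panel per pair of labels; red points stood apart from level-matched random lists in both assays. In WT over MT the interferon and NF-kappaB lists lie at 0.27 and 0.28 in RNA-seq and at -0.27 and -0.29 in Ribo-seq; red lists and lists far from 0 carry short names, and marker lists are left out.

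Translational efficiency was taken as the Ribo-seq log2 ratio minus the RNA-seq log2 ratio. In WT over EV 310 genes were higher and 233 lower (133 and 86 at a minimum of 10 units), led by COMMD3-BMI1, TVP23C, DUSP16, SCN8A and NOTCH2NLA upward and by NOTCH2NLC, RREB1, ARL2-SNX15, EXOG (log2 of -2.12) and NEMP2 downward. For EXOG the mRNA value was higher in WT and the Ribo-seq value rose by less (6.88 TPM in EV and 9.72 in WT). G2 and M phase genes (0.24), peroxisome and fatty acid oxidation (0.19), NRF2 targets (0.18) and nuclear-encoded oxidative phosphorylation (0.17) were high. Antigen presentation (-0.40), immediate early (-0.27), ribosome biogenesis (-0.24), heat shock (-0.22), matrix (-0.19), NF-kappaB (-0.18), interferon-stimulated (-0.18), VHL-null line (-0.16) and histone genes (-0.11) were low, of which the NF-kappaB and VHL-null lists no longer stood apart at a minimum of 10 units. Other settings gave 219 to 1176 genes. With the WT and MT labels exchanged in Ribo-seq, 167 of the 543 genes were shared, and TVP23C (0.12), DUSP16 (0.12) and SCN8A (0.40) no longer passed the rule. The antigen presentation (0.04), immediate early (0.04), matrix (0.02), interferon-stimulated (0.08) and VHL-null medians (0.06) changed side, and of the lists named here only ribosome biogenesis (-0.31), heat shock (-0.28) and oxidative phosphorylation (0.09) stood apart as before.

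In MT over EV 288 genes had a higher and 169 a lower translational efficiency (113 and 57 at a minimum of 10 units). FAM72D, ST20-MTHFS, SCHIP1, PHYHD1 (log2 of 3.16) and NOTCH2NLB were highest, and RREB1, EXOG (-2.79), FAM72A, NOTCH2NLC and NEMP2 lowest. PHYHD1 stood at 0.092 FPKM and 0 TPM in EV, so its value over EV depends largely on the added 1 and is not a measured efficiency. SCHIP1, like ARL2-SNX15 above and H4C13 and H3C3 below, has no usable mRNA value behind its translational efficiency. The same holds, here and above, for the histone list, whose median mRNA value was 0.072 to 0.145 FPKM. Interferon-stimulated genes (0.37), mitochondrially encoded mRNAs (0.30), ATF4 targets (0.27), antigen presentation (0.22), hypoxia-inducible factor targets (0.18), aminoacyl-tRNA synthetases (0.16) and matrix genes (0.13) were high. Histones (-0.17), heat shock genes (-0.16), ribosome biogenesis (-0.14), proteasome (-0.13) and G2 and M phase genes (-0.09) were low. At a minimum of 10 units the antigen presentation and matrix lists no longer stood apart, and the settings gave 170 to 1093 genes. With exchanged Ribo-seq labels 168 of the 457 genes were shared, and ST20-MTHFS (-0.20) and FAM72A (0.67) changed sign and no longer passed. PHYHD1 was then at 1.14, again against an EV without usable values. Antigen presentation (-0.30), matrix (-0.13) and G2 and M phase genes (0.13) changed side, and of the lists named here only ATF4 targets (0.38), aminoacyl-tRNA synthetases (0.27) and histones (-0.16) stood apart as before.

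In WT over MT 291 genes were higher and 338 lower in translational efficiency (119 and 124 at a minimum of 10 units). TVP23C, DUSP16, ARPIN, TVP23C-CDRT4 and FAM72A were highest, and ARPIN-AP3S2, ST20-MTHFS, TGM2 (log2 of -3.09), H4C13 and H3C3 lowest. TGM2 had more mRNA in WT than in MT and a lower Ribo-seq value (6.88 and 24.9 TPM). Among lists, interferon-stimulated genes (-0.51), antigen presentation (-0.49), NF-kappaB (-0.49), immediate early (-0.43), matrix (-0.33), mitochondrially encoded (-0.26) and ATF4 genes (-0.23) were low. The median of 7 renal tubule markers was low too (-0.51), with 5 of them below 0 and 2 above. Of these markers 1 passed the rule downward and 2 upward. The median of the fibroblast markers given below was also low, and G2 and M phase genes (0.24) were high. Of 37 lists 16 were low and 6 high. Other settings gave 243 to 1299 genes. With the WT and MT labels exchanged in Ribo-seq, 442 genes passed, of which 202 were shared with the 629 of the deposited labels. All 10 genes named in this paragraph changed sign, TGM2 to 0.35, inside the rule. The exchange turns every Ribo-seq difference of WT over MT by construction. A gene whose Ribo-seq difference is larger than its mRNA difference therefore had to change sign. The list medians then were -0.03 for interferon-stimulated, 0.24 for antigen presentation, -0.003 for NF-kappaB, 0.17 for immediate early, 0.12 for matrix, 0.41 for mitochondrially encoded, -0.29 for ATF4 and -0.10 for G2 and M phase genes, so of these only the ATF4 list stood apart on the same side under either labelling. The Ribo-seq median of the ATF4 list was 0.03 and its RNA-seq median 0.26, so its value rests mainly on RNA-seq.

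Differences between labels in the 2 assays were weakly related across genes, which are not independent replicates. Over 1216 genes at 50 units or more in all 6 libraries, the RNA-seq and Ribo-seq log2 ratios of WT over MT had a Pearson r of -0.22 (95% bootstrap interval over genes -0.28 to -0.15). Over 4836 genes at 10 units or more in each library compared r was -0.15. For WT over EV r was 0.05 and for MT over EV -0.05, with intervals that included 0. Among genes at 10 units or more in all 6 libraries, mRNA differed by a log2 of 0.5 or more between WT and MT in 75. Of these, 17 (22.7%) had a Ribo-seq difference of the same sign, and of 23 genes with 0.7 or more, 4 did. Of genes past the RNA-seq rule and measured in both assays, 8 of 26 higher and 7 of 17 lower had the same sign. Few genes passed the rule in the same direction in both assays. The counts exceeded the 0.13 to 0.31 per direction expected if the assays were independent, except in WT over MT upward (0 genes). The other directions had 1 to 3 genes each, PHYHD1 and readthrough names among them. That expectation was not matched on level, and calls in both assays lie mostly at low levels. The excess therefore does not show that the assays go together. In WT over EV the genes that passed in the same direction were PHYHD1, C21orf91 (3.84 to 9.30 FPKM and 4.55 to 10.5 TPM), ABHD14A-ACY1 and, downward, the myosin phosphatase subunit gene PPP1R12B. In MT over EV they were PHYHD1, ASTE1 and, downward, CHURC1-FNTB, and in WT over MT RPL36A-HNRNPH2 downward; ABHD14A-ACY1, CHURC1-FNTB and RPL36A-HNRNPH2 are readthrough names and uncertain. Calls in opposite directions numbered 4 among genes with higher and 2 among those with lower mRNA in WT over MT, and 2 among those lower in WT over EV.

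The reference genes stayed inside the 2-fold rule in every comparison. VEGFA came closest to it, with a log2 of -0.99 in translational efficiency for WT over MT. VHL mRNA was 13.5, 14.5 and 15.6 FPKM in EV, WT and MT. EPAS1, which encodes HIF-2alpha, stood at 16.6, 16.5 and 12.1 FPKM and at 6.32, 4.996 and 6.56 TPM in Ribo-seq. VEGFA stood at 59.6, 63.7 and 46.5 FPKM and at 36.3, 21.9 and 32.2 TPM in Ribo-seq. CCND1 (cyclin D1) stood at 68.8, 62.2 and 53.6 FPKM and at 134.7, 114.3 and 139.0 TPM. GAPDH mRNA was 2303, 2386 and 2359.7 FPKM. ACTB stood at 1619, 1889 and 1815 FPKM and at 12118, 9676 and 10930 TPM in Ribo-seq, so its mRNA value was lowest and its Ribo-seq value highest in EV, also after median-ratio scaling. Of the markers of other cell types, 2 of 22 leukocyte genes, 1 of 15 endothelial, 4 of 16 hepatocyte, 5 of 13 fibroblast and 0 of 11 erythroid genes reached 1 unit, and 4 of 13 genes of the HEK293 line did, among them UCHL1 at 563, 546 and 601 FPKM in EV, WT and MT. The 5 fibroblast markers were at a median of -0.56 in Ribo-seq and -1.15 in translational efficiency for WT over MT, at levels near the minimum.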

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

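Of the tests below, those of exchanged labels, opposing translation and library scaling were chosen after the results they bear on had been seen; the tests of trends and of error by level were set beforehand. None of the differences between assays listed here was itself tested, since each assay has 1 library per label.

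Several lists moved in opposite directions in RNA-seq and Ribo-seq while standing apart in both. For WT over MT the Ribo-seq median minus the RNA-seq median was -0.53 for interferon-stimulated genes, -0.57 for NF-kappaB and inflammatory genes, -0.36 for extracellular matrix genes and 0.29 for G2 and M phase genes. For WT over EV it was -0.38 for the NF-kappaB list and -0.21 for the matrix list. In RNA-seq 4 of these did not hold at a minimum of 10 units, where the NF-kappaB list in WT over EV (-0.0096) and the matrix list in WT over MT (-0.0082) reversed, and the matrix list in WT over EV (percentile 74.1) and the NF-kappaB list in WT over MT (97.46) ceased to stand apart. In MT over EV mitochondrially encoded mRNAs differed by 0.38. PHYHD1 differed by 2.13 for MT over WT.

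Across genes, too, WT and MT differed in opposite directions in the 2 assays (r of -0.22 over 1216 genes, and -0.25 over the 828 that belong to no list). A trend with level or gene span is argued against, since r was -0.221 after the medians within deciles of RNA-seq level, Ribo-seq level and span had been removed. A crossing of the WT and MT labels between the assays and opposing translation of changed mRNAs cannot be told apart, since the correlations over EV are tied to the WT over MT correlation and no value independent of it decides. Either may account for the pattern. With 1 library per label and assay, differences between libraries that have nothing to do with the labels are not excluded. The bootstrap over genes does not cover such differences. RNA-seq WT over EV correlated with Ribo-seq MT over EV at r of 0.0977 (interval 0.03 to 0.16, which includes the 0.05 of the uncrossed pair), and RNA-seq MT over EV with Ribo-seq WT over EV at 0.16 (0.11 to 0.22, which lies above both uncrossed r of 0.05 and -0.05). The criterion for crossed labels was rewritten with these values known, more than once, and the earlier forms, which would have gone with crossed labels, are not counted. For opposing translation, the mean r of the uncrossed pairs was 0.00021 (interval -0.05 to 0.05). Signs of mRNA differences were compared for genes at 10 units or more in all 6 libraries. They matched uncrossed and crossed Ribo-seq in 30 and 37 of 61 genes (WT over EV, log2 of 0.5 or more), 8 and 5 of 13 (0.7 or more), 14 and 23 of 36 (MT over EV, 0.5) and 4 and 10 of 15 (0.7). These counts are tied to the WT over MT pattern in the same way.

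PHYHD1 had a Ribo-seq value 4.08 times higher in MT than in WT at about equal mRNA. Genes at 100 units or more did not share this difference, as their median Ribo-seq log2 ratio of MT over WT was -0.0176. Each Ribo-seq library is scaled to one total, so a median near 0 was largely set in advance and does not test library scaling. Exchanging the Ribo-seq labels does not even out the ratios of Ribo-seq to RNA-seq, which still differ 3.80-fold, so a label exchange would turn the direction of the difference and leave its size. Construct sequences, codon usage and how footprints on the deleted segment were counted may also matter and were not tested, and a biological difference between the proteins' mRNAs in translation stays open as untested.

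More genes passed the 2-fold rule in Ribo-seq (304 to 359) than in RNA-seq (32 to 56). The added 1 weighs more in RNA-seq, whose columns sum to 459938 to 469859 against 1000000 in Ribo-seq. With a pseudocount of 0.1 the counts were 660 to 727 in Ribo-seq and 145 to 198 in RNA-seq. An error that grows as levels fall may account for much of the excess. PHYHD1 is left out of the shares and counts by level given here. In Ribo-seq the share past the rule at 100 units or more was at least 28.5 times below that at 1 to 10 units. In each of these comparisons 1 to 3 genes passed at 100 units or more. In RNA-seq the share was 3.28 and 3.40 times lower in the comparisons with WT. In MT over EV 0 genes besides PHYHD1 passed at 100 units or more. At that level the share was 0% to 0.274% in RNA-seq and 0.065% to 0.193% in Ribo-seq, so the excess of Ribo-seq lies at lower levels. Simulated counting error alone gave 0.642% of unchanged Ribo-seq genes at 1 to 10 units in WT over EV, against 6.16% observed. The simulation gave every gene the same value per read and both libraries the same depth. Genes whose reads are worth more hold fewer reads than simulated, so it cannot decide whether counting error falls short. Real differences in translation would add to the count and were not tested apart from error.

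Outside the genes analysed, 3 rows without a gene name were at least 2-fold above EV in both other Ribo-seq libraries, of 82 such rows at 10 units or more. Their EV, WT and MT values were 2.17, 9.85 and 11.04 TPM, 9.97, 28.2 and 25.4 TPM, and 6.13, 13.5 and 14.4 TPM.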

How the results depend on the processing

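No paired analysis was possible because each label has 1 library per assay, and for the same reason no library could be left out. The alternatives with a minimum of 1 unit in every library compared and with exchanged Ribo-seq labels were chosen after the data were seen. Counts below are in the order WT over EV, MT over EV, WT over MT. Median-ratio scaling and a minimum of 0.1 unit kept all 27 counts (total, higher and lower in 9 comparisons) within 1.5 times. With 1 added to each value, a gene under 1 unit in both libraries compared cannot pass the rule within an assay. The minimum of 0.1 unit therefore could change only the counts of translational efficiency. Scaling shifts a list and its random lists nearly alike, so it does not test the list medians. After it 111 of 112 named values stayed past the rule, the other being SMPDL3A in RNA-seq WT over EV (just inside the rule). The shift of the median of all genes stayed under 0.04. PHYHD1 after scaling was 0.0917, 117.6 and 109.8 FPKM in EV, WT and MT, and 219 and 906 TPM in WT and MT. A minimum of 10 units, which tests fewer genes, moved every total: RNA-seq 15, 9 and 15, Ribo-seq 90, 85 and 101, translational efficiency 219, 170 and 243 (main values RNA-seq 55, 32 and 56, Ribo-seq 359, 304 and 343, translational efficiency 543, 457 and 629). A pseudocount of 0.1, which enlarges ratios of low genes, gave RNA-seq 177, 145 and 198, Ribo-seq 694, 660 and 727, and translational efficiency 1176, 1093 and 1299. With 1 unit in every library compared, the totals were RNA-seq 29, 20 and 34, Ribo-seq 205, 194 and 194, and translational efficiency 317, 269 and 371; genes near 0 in 1 library drop out by construction, PHYHD1 over EV among them. Exchanged labels gave 437, 478 and 442 for translational efficiency, with 167, 168 and 202 genes shared with the main calls. Of the list medians at a minimum of 10 units, 288 stood apart or not as before, 11 ceased to stand apart, 11 came to do so, and 2 reversed: NF-kappaB genes in RNA-seq WT over EV (-0.0096, main 0.13) and matrix genes in RNA-seq WT over MT (-0.0082, main 0.13); these lists hold many genes under 10 units, which that minimum removes. Calls under 10 units made up 71.9% to 73.2% in RNA-seq and 70.6% to 74.9% in Ribo-seq. With exchanged labels 12 of 30 named values of translational efficiency reversed: in MT over EV ST20-MTHFS (-0.198) and FAM72A (0.67), and in WT over MT TVP23C (-3.06), DUSP16 (-2.08), ARPIN (-2.44), TVP23C-CDRT4 (-2.62), FAM72A (-2.72), ARPIN-AP3S2 (3.69), ST20-MTHFS (4.36), TGM2 (0.348), H4C13 (3.07) and H3C3 (3.05). In WT over EV 3 were inside the rule. Reversals in WT over MT were bound to occur where the Ribo-seq difference was larger than the mRNA difference. Of 109 list medians 17 reversed, 19 ceased to stand apart and 15 came to do so. The reversed lists were, in WT over EV, immediate early (0.0376), interferon-stimulated (0.0756), antigen presentation (0.0414), matrix (0.0232) and VHL-null line genes (0.058); in MT over EV, G2 and M phase (0.134), antigen presentation (-0.296) and matrix genes (-0.132); and in WT over MT, immediate early (0.173), hypoxia-inducible factor target (0.0055), mitochondrially encoded (0.413), G2 and M phase (-0.0985), antigen presentation (0.244), matrix (0.124) and proteasome genes (-0.0729) and fibroblast (0.0974) and renal tubule markers (0.39).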

Other observations

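The genes and groups in this part were chosen after their values were seen, although the histone and mitochondrial lists were fixed beforehand.

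Replication-dependent histone genes, which encode the core and linker histones made in S phase, were nearly absent from RNA-seq and abundant in Ribo-seq. The median over the 47 histone genes in the table was 0.072, 0.103 and 0.145 FPKM in EV, WT and MT, against 973, 924 and 889.7 TPM. H3C2 and H4C5, the most abundant, stood at 3142 and 2826 TPM in EV. Histone genes have many near-identical copies, and their translational efficiency has no usable mRNA value behind it.

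MT-ATP8 held most of the mitochondrially encoded Ribo-seq signal, with 11621 TPM in EV and 21537 TPM in MT, whereas its mRNA was 1796 and 1284 FPKM. MT-CO1 and MT-CO2, by contrast, were at 429 and 186 TPM in EV with mRNA values of 12177 and 12400.4 FPKM. Its short reading frame overlaps that of MT-ATP6, so how reads of the overlap were assigned bears on its value.

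Single genes gave examples of opposite differences between the libraries labelled WT and MT. CSF1 stood at 36.6 and 21.7 FPKM in RNA-seq and at 30.1 and 44.7 TPM in Ribo-seq. ERRFI1 was at 116 and 69.2 FPKM and at 45.2 and 64.7 TPM, and TRIM55 at 36.9 and 20.95 FPKM and at 25.7 and 41.8 TPM. NT5E was at 25.5 and 8.49 FPKM and at 15.97 and 41.2 TPM.

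Across 9712 genes the Pearson r of log2 levels was 0.991 to 0.992 between RNA-seq libraries and 0.985 to 0.988 between Ribo-seq libraries, and 0.778 to 0.787 between the assays. Such an r reflects mainly the wide spread of levels between genes.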
